A study of Mus musculus with 20 samples.

How the data were processed

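RNA was measured on 1-colour Affymetrix MOE430 2.0 arrays in 20 pools of mouse blastocysts of the CF1 strain, each pool made of 20 embryos, 400 embryos in all. Per the labels, the pools fell into 5 groups of 4 replicates: untreated embryos, embryos exposed to calcium- and magnesium-free medium (CMF), embryos exposed to acid Tyrode's solution (acid), embryos exposed to both (CMF_acid), and embryos from which a blastomere was taken after both exposures (biopsy). Per the series design text, the embryos were handled at the 8-cell stage and collected 96 h after hCG, and the RNA of each pool went through linear amplification in repeated rounds before labelling with biotin. The replicates are numbered from 2 to 5 in every group. Nothing in the labels says which pools shared a collection day, so the p-values measure only the spread between these pooled samples, which may in part be technical.

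The values used for all main results were the authors' deposited intensity values of the series table, 1 per probe set and array. Per the series design text, the authors made these intensity values with the GC-RMA algorithm in ArrayAssist Lite 3.4, which subtracts background by probe sequence, normalizes between arrays and summarises the probes. The deposited values are on the linear scale, and per the same text the authors took log2 only later, for GeneSpring 7.31 and Partek Genomics Suite 6.3. Each array also has its own deposited table with an intensity per probe set from the Affymetrix statistical algorithm, scaled array by array, a detection call and a detection p-value. Per the file headers, the p-value in these deposited tables comes from the detection test of the same software, whose version is not given in the sources used here. The software signal served as an alternative summary and the detection calls for the filter.

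The table held 45101 probe sets. The 64 control probe sets were left out, and 25553 probe sets with a Present call on 3 or more arrays were tested, the filter that the series design text gives. The platform annotation listed 35890 probe sets, 34958 with a single gene symbol and 932 with several, while 9160 were not listed. Symbols were updated through the gene number where it matched the mouse gene table, which it did for 34754 probe sets. Of the tested probe sets, 21292 carried a single symbol, and no gene was named from a probe set with several. For gene lists, each of the 12025 genes was represented by its tested probe set with the highest mean over all 20 arrays.

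Deposited intensities were log2 transformed, and limma 3.58.1 in R 4.3.3 was fitted per probe set with lmFit and eBayes, all 20 arrays in a single fit with 5 group means so that the groups shared an estimate of the spread. The 7 comparisons were each treatment against untreated, biopsy against CMF_acid, the CMF by acid interaction, and the mean of the 4 treatments against untreated. A moderated F test asked for any difference among the 5 groups. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and a probe set was called at an adjusted p under 0.05. For values per array, such as list scores, exact permutation tests over the 70 assignments of 4 against 4 arrays were used, whose smallest possible p is 0.0286. Standard errors given with log2 differences are those of limma, with n = 4 arrays per group.

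Before the data were examined, 27 gene lists were fixed, covering the lineages of the blastocyst, maternal and early embryonic transcripts, stress responses, junctions and ion transport, acid-base and calcium handling, signalling, the cell cycle, chromatin, imprinting, metabolism, implantation and sex-linked genes. The tests, the filter, the samples in each fit, the rule for naming genes and most alternative settings were fixed at the same time. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within each comparison, where at least 5 members were tested. This left 26 lists holding 516 genes. The list of cumulus and granulosa cell markers had 4 tested members of 17 and was not tested. Each list was also tested with camera at an estimated correlation, with fry, and by exact permutation of the arrays' list scores, a score being the mean over members of the log2 deviation from the mean of all arrays.

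The rule for named genes took, in each comparison, up to 10 genes per direction among probe sets past the threshold with all 4 treated arrays on the same side of the control mean, filled where too few passed with those of the lowest unadjusted p, given as values that did not pass. Since no probe set passed, every single gene named under this rule is of the second kind, and the text gives the leading genes of each direction. Of each list described, up to 4 members with the lowest p were eligible. Genes named from single arrays, from the spread within groups or from the replicate numbers were chosen after their values were seen.

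Power was tested by adding known changes at 200 of the 25553 probe sets to the real arrays in 20 draws for biopsy against untreated. The changed probe sets were drawn only from those above a set mean level, and changes of all sizes were added together. The shares below therefore do not cover weak signals or a setting with few changes. At a 1.5-fold change 37.5% of them were recovered, at a 2-fold change 77.2%, and at a 4-fold change 98.7%. For camera, the values were instead simulated noise in which the genes varied independently. There, a list shifted by 0.30 log2 was called in 20 of 20 draws in the same comparison, on 12025 genes. Independent genes cannot show how often camera calls unshifted lists where genes vary together, so these draws do not bear on that. In the real data, the median standard error of a difference between a pair of groups was 0.14 log2. The 95% interval lay within a 2-fold change for 95.9% of the probe sets in biopsy against untreated and within a 1.5-fold change for 76.9%. The number of arrays limits this precision.

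Alternatives fixed in advance were no detection filter and a stricter one, median centring, the software signal, eBayes with trend and robust settings, array quality weights, ordinary least squares, other thresholds, the Gapdh 3 prime to 5 prime ratio as a covariate, the replicate number as a block, fits on only the groups compared, the mean of all probe sets of a gene, other list tests, and leaving out each array in turn. Alternatives without CMF_acid replicate 5 where these were not planned, the block combined with that omission, and the exact permutation of list scores were added after seeing the data.

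The replicate numbers come from the sample titles. Deviations from the group means were correlated over the probe sets between same-numbered arrays. In acid against untreated all 4 correlations were over 0.1, at 0.313, 0.233, 0.124 and 0.202, so those numbers were taken to pair the arrays and a blocked value is given where it changes a call. In the other comparisons at least 1 correlation was lower, and the arrays were treated as sharing only a number. Biopsy and acid arrays of the same number also passed this limit, at 0.31, 0.21, 0.24 and 0.24. So did CMF and acid arrays, at 0.16, 0.32, 0.29 and 0.25. The limit therefore does not show that the arrays of the other comparisons were unpaired. All 20 arrays correlated best with an array of their own number. Deviations shared by a number stay in the spread of the unblocked fits. Counts at an unadjusted p under 0.05 that lie below chance are therefore not by themselves evidence of no effect.

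The lists without a call in biopsy against untreated had these camera adjusted p-values. Trophectoderm markers were at 0.686, oocyte and maternal transcripts at 0.251, zygotic genome activation genes at 0.884, p53 targets at 0.998, apoptosis machinery at 0.628 and heat shock proteins at 0.884. The unfolded protein and integrated stress response was at 0.628, the oxidative stress response at 0.556, immediate early genes at 0.0530, junction genes at 0.884 and blastocoel ion and water transport at 0.251. Acid-base regulation was at 0.0899, calcium and magnesium handling at 0.780, the Hippo pathway at 0.396, cell cycle genes at 0.364, imprinted genes at 0.884 and chromatin regulators at 0.639. Glycolysis was at 0.884, cholesterol synthesis at 0.998, implantation-related genes at 0.467 and sex-linked genes at 0.884. In the other comparisons the lists not described had adjusted p-values between 0.0745 and 0.998. The median, the mean and the camera direction of a list differed in sign for 8 lists in biopsy, 8 in CMF, 7 in acid, 5 in CMF_acid, 10 in biopsy against CMF_acid, 5 in the interaction and 10 in the mean of the 4 treatments, and for 0 of the called lists. With all 20 arrays, 0 lists were called by camera at the estimated correlation, by fry or by exact permutation of the scores in any comparison where these were run.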

Results

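Gene expression was profiled in 20 pools of mouse blastocysts, 4 pools in each of 5 groups, to ask whether embryo biopsy, the removal of a blastomere at the 8-cell stage, or the exposures that go with it, alter transcripts at the blastocyst stage. CMF medium lacks the calcium and magnesium that cell adhesion needs and loosens the blastomeres, and acid Tyrode's solution opens the zona pellucida, the glycoprotein coat of the embryo. Between 44.3% and 50.9% of the probe sets were called Present per array, with a mean of 49.0% ± 1.45 (SD, n = 20). The group means were 48.6% ± 0.480 for untreated, 49.2% ± 1.23 for CMF, 49.2% ± 0.674 for acid, 48.1% ± 2.78 for CMF_acid and 49.9% ± 0.899 for biopsy (SD, n = 4 each). The 3 prime to 5 prime ratio ranged from 3.08 to 4.30 for Gapdh and from 1.51 to 4.22 for actin. CMF_acid replicate 5 had the actin ratio of 4.22 and stood apart, with a mean correlation of 0.985 with the other 19 arrays, whose own mean correlations were 0.994 or higher.

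The untreated blastocysts expressed markers of all lineages of this stage. Dppa5a and Pou5f1, genes of the pluripotent inner cell mass, had mean log2 intensities of 15.76 ± 0.01 and 14.47 ± 0.09 (SD, n = 4). Krt8, a keratin of the trophectoderm, the outer epithelium, stood at 15.25 ± 0.03 and its partner Krt18 at 14.97 ± 0.14. The primitive endoderm is the layer that lines the cavity. Of its markers, measured in whole blastocysts, the endocytic adaptor Dab2 stood at 14.58 ± 0.08 and the transcription factor Gata6 at 13.37 ± 0.05. Others of that list had low signals, such as Gata4 at 3.05 ± 0.41 and Sox7 at 2.85 ± 0.01. Of the listed members, 20 of 25 inner cell mass and epiblast markers, 19 of 25 trophectoderm markers and 14 of 24 primitive endoderm markers were tested and called Present in all 4 untreated arrays. Transcripts of the oocyte such as Ooep and Nlrp4f remained detectable at 10.15 ± 0.19 and 10.17 ± 0.13. Of the 17 listed markers of cumulus and granulosa cells, which surround the oocyte, 3 were, among them Amhr2 at 9.27 ± 0.41.

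**Figure D1:**
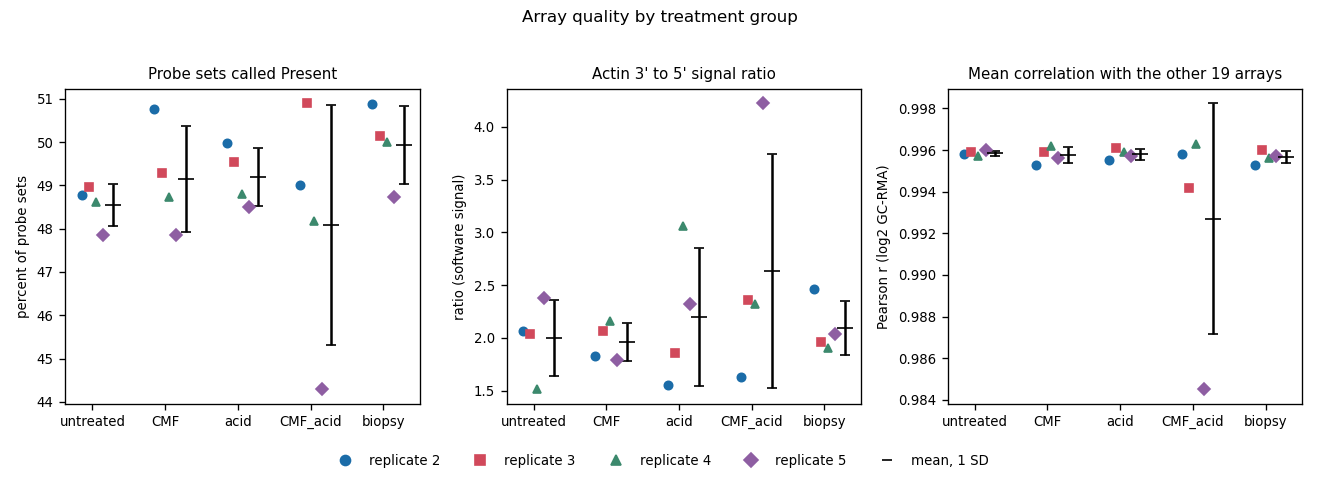
Per array, the share of probe sets called Present (percent), the actin 3 prime to 5 prime ratio and the mean correlation with the other 19 arrays are plotted by group, 1 point per array with bars for the group mean and 1 SD (n = 4). CMF_acid replicate 5 has the highest actin ratio, 4.22, and the lowest mean correlation, 0.985.

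Biopsied embryos were compared with untreated embryos to take in the whole procedure. By camera, primitive endoderm markers were lower in the biopsied embryos, with 15 of 20 members lower and a median difference of -0.22 log2 (adjusted p = 1.41e-08). The adjusted p = 0.0907 with an estimated correlation, above the threshold, and the list scores of the arrays differed with an exact permutation p of 0.0571. Serpinh1, a chaperone of collagen folding, was called Present in 4 untreated arrays and 0 biopsy arrays, so that its fitted difference of -1.44 ± 0.42 log2 (SE, n = 4) has no measured size on the biopsy side. With any 1 member left out, the unadjusted camera p of the list was at most 2.32e-08. Cubn, an endocytic receptor for vitamins and proteins, differed by -0.66 ± 0.20, Col4a1, a collagen of the basement membrane, by -0.34 ± 0.12 and P4ha2, a collagen prolyl hydroxylase, by -0.27 ± 0.10. Serpinh1 and Cubn passed when adjusted over the list alone, both at an adjusted p of 0.0437, and neither did over all probe sets. The mean log2 level of Serpinh1 was 7.70 in untreated, 6.87 in CMF, 7.14 in acid, 6.71 in CMF_acid and 6.26 in biopsied embryos, with Present calls in 1, 1, 0 and 0 of the 4 arrays of these treated groups.

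Inner cell mass and epiblast markers were also called lower after biopsy by camera, with 15 of 22 members lower and a median of -0.04 log2 (adjusted p = 0.0263, adjusted p = 0.580 with an estimated correlation). Gdf3, a growth factor of pluripotent cells, differed by -0.31 ± 0.12 and Tdgf1, a co-receptor for Nodal, by -0.48 ± 0.23 (SE, n = 4). Bmp4, a signalling factor of the epiblast, differed by -0.78 ± 0.42. Among oxidative phosphorylation genes 20 of 26 were lower, with a median of -0.04 (adjusted p = 0.0138, adjusted p = 0.580 with an estimated correlation), and Sdhb of the succinate dehydrogenase complex differed by -0.17 ± 0.07. Among genes of ribosomal proteins 13 of 18 were lower, with a median of -0.03 (adjusted p = 0.0263, adjusted p = 0.580 with an estimated correlation). Among genes of the cytoskeleton and apical microvilli 21 of 25 were lower, with a median of -0.03 (adjusted p = 0.0359, adjusted p = 0.580 with an estimated correlation), with beta-tubulin Tubb5 at -0.23 ± 0.10. Leaving out 1 array ended the epiblast call for biopsy replicate 2 or 4, untreated replicate 4 or 5 or CMF_acid replicate 5, the last at an adjusted p of 0.0592. It ended the oxidative phosphorylation call for untreated replicate 2 or biopsy replicate 4 or 5. The ribosomal call was lost without replicate 2, 4 or 5 of biopsy or 2, 3 or 5 of untreated, and the cytoskeleton call without biopsy replicate 2 or 4, untreated replicate 3 or 5 or CMF_acid replicate 5. These calls reached adjusted p-values of up to 0.226, 0.226, 0.439 and 0.392 in that order. With the software signal all 4 calls ended, the epiblast list at 0.451 and the others at 0.119, and the oxidative phosphorylation call also ended with the mean of all probe sets of a gene, at 0.0890. The primitive endoderm call stayed under an adjusted p of 1.08e-04 or less with any 1 array left out.

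Trophectoderm markers were not called, with 12 of 22 higher and a median of 0.03 log2 (adjusted p = 0.686). Within the list, Cdx2, the transcription factor that sets the lineage, differed by 0.16 ± 0.12, and Aqp3, a water channel, by -0.36 ± 0.11. Of the oocyte and maternal transcripts 10 of 14 were higher (adjusted p = 0.251). Nlrp5 and Nlrp14, maternal-effect genes of the oocyte, differed by 0.30 ± 0.08 and 0.65 ± 0.21 and passed when adjusted over the list alone, at 0.0271 and 0.0410. Nlrp5 was called Present in 0 untreated and 2 biopsy arrays, so its size was not measured on the untreated side. It was also called Present in 2 CMF and 2 acid arrays. Adjustment over a list alone takes no account of the other lists and comparisons, and neither gene passed over all probe sets. Targets of p53, the regulator of the DNA damage response, were divided, 11 of 19 higher, with a median of 0.01 (adjusted p = 0.998). Of the immediate early genes, which respond to stimulation within minutes, 15 of 19 were higher, with a median of 0.06 (adjusted p = 0.0530).

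No single gene passed in biopsy against untreated. Limma called 0 of 25553 probe sets, the lowest adjusted p was 1, and ordinary least squares also called 0. At an unadjusted p under 0.05 there were 535 probe sets by limma, 350 higher and 185 lower, and 480 by ordinary least squares, where chance gives about 1278 if the arrays are independent. The genes with the lowest unadjusted p, none of which passed, included Tmx3, a protein disulfide isomerase of the endoplasmic reticulum, at 0.60 ± 0.12, and Cdc27, a subunit of the anaphase-promoting complex, at 0.38 ± 0.08. The importin Kpna1 stood at 0.39 ± 0.09, the mitochondrial leucyl-tRNA synthetase Lars2 at 0.93 ± 0.22, the ubiquitin ligase subunit Fbxw7 at 0.47 ± 0.13 and the prion protein gene Prnp at 0.58 ± 0.16. On the lower side were the sugar-phosphate transporter Slc37a2 at -0.50 ± 0.14, the junction protein Jam2 at -0.67 ± 0.19 and Bsg, a membrane glycoprotein that accompanies lactate transporters, at -0.19 ± 0.06. The other tested probe set of Lars2 and that of Fbxw7 had the opposite sign. Lars2 had a low log2 signal in untreated arrays, 3.89 in replicate 2 and 4.63 to 4.77 in the others. The median level of the tested probe sets was 7.82. Without CMF_acid replicate 5, an omission chosen after seeing the data, 0 probe sets were called, 1042 were at an unadjusted p under 0.05, and the called lists were primitive endoderm markers (adjusted p = 2.65e-07, adjusted p = 0.264 with an estimated correlation), oxidative phosphorylation (0.00441) and ribosomal proteins (0.0376, both at an adjusted p = 0.794 with an estimated correlation). Without untreated replicate 5, Zfp78, a zinc finger gene at a low mean log2 of 3.74, was called at -0.50 (adjusted p = 6.91e-04).

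**Figure D2:**
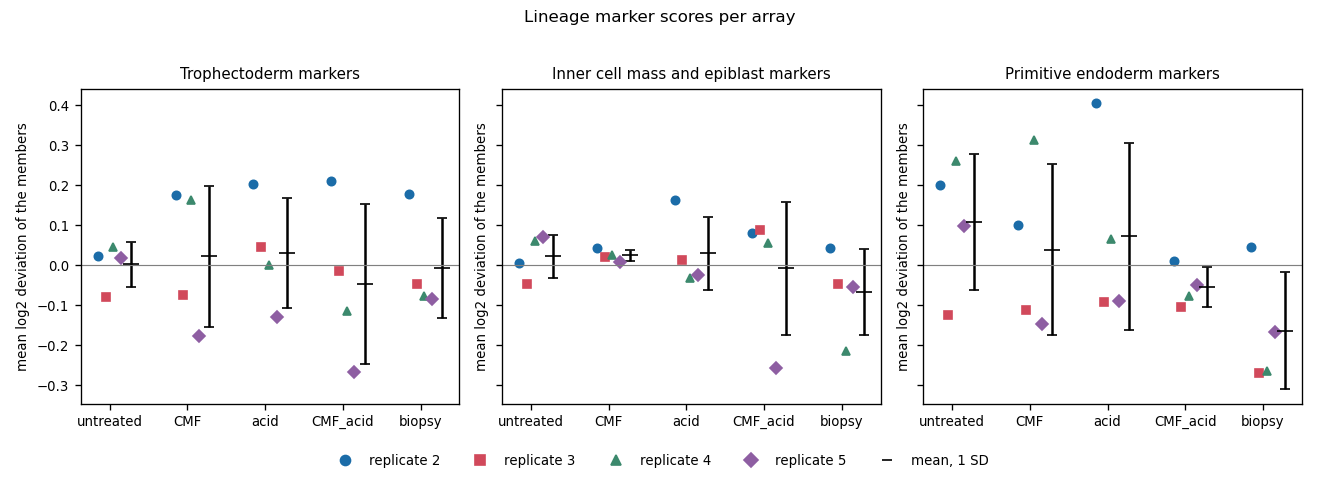
List scores (mean log2 deviation from the mean of all 20 arrays) of the lineage markers are plotted by group, 1 point per array with bars for the group mean and 1 SD (n = 4). All 4 biopsy arrays lie below the mean of the untreated arrays for primitive endoderm markers. So do the CMF_acid arrays, which reach at most 0.011 against an untreated mean of 0.108. Untreated and biopsy arrays overlap, with a lowest untreated score of -0.125 and a highest biopsy score of 0.045.

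Embryos exposed to CMF alone were compared with untreated embryos to separate the loosening of cell contacts. By camera, p53 targets were lower, with 16 of 19 members lower and a median of -0.15 log2 (adjusted p = 0.0486, adjusted p = 0.996 with an estimated correlation). Phlda3, an inhibitor of Akt signalling, differed by -0.46 ± 0.31 and Bbc3, a pro-apoptotic member of the Bcl2 family, by -0.18 ± 0.14 (SE, n = 4), while Gadd45a, a growth arrest gene, differed by 0.24 ± 0.14. This call was lost without any of 13 of the arrays, namely replicate 2, 4 or 5 of biopsy, 2, 3 or 5 of CMF, 2, 3 or 5 of CMF_acid, 2 or 4 of untreated and 4 or 5 of acid, with an adjusted p of up to 0.817, and of 0.144 without CMF_acid replicate 5. It also ended with the software signal, at 0.125, and with no detection filter, at 0.222. Primitive endoderm markers had a median of -0.01, with 13 of 20 lower (adjusted p = 0.506), and oxidative phosphorylation genes one of -0.02, with 17 of 26 lower (adjusted p = 0.242). Among single genes that did not pass, Tpm3, a tropomyosin of the actin cytoskeleton, stood at 0.58 ± 0.14, D2hgdh, a mitochondrial dehydrogenase, at 0.50 ± 0.14 and the dynactin subunit Dctn4 at 0.18 ± 0.05. Rmi1, a partner of the Bloom helicase, stood at -0.29 ± 0.09, the homeobox gene Hesx1 at -0.63 ± 0.22 and Ncbp3, a cap-binding protein, at -0.97 ± 0.33. All 4 other tested probe sets of Rmi1, 3 of the 4 others of Dctn4 and the other ones of D2hgdh and Ncbp3 had the opposite sign. Limma and ordinary least squares each called 0 probe sets, with 258 and 246 at an unadjusted p under 0.05 and a lowest adjusted p of 1. Without CMF_acid replicate 5, 0 probe sets and 0 lists were called. Without untreated replicate 5, Zfp78 was called at -0.52 (adjusted p = 4.56e-04).

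Embryos exposed to acid Tyrode's alone were compared with untreated embryos to separate the opening of the zona. Genes of adherens and tight junctions and desmosomes, which seal the outer epithelium, were higher by camera, with 24 of 26 members higher and a median of 0.09 log2 (adjusted p = 4.44e-04, adjusted p = 0.516 with an estimated correlation). Cldn6, a claudin of tight junctions, differed by 0.41 ± 0.20 and Pard3, a polarity protein, by 0.19 ± 0.09 (SE, n = 4). Targets of p53 were lower, with 18 of 19 lower and a median of -0.16 (adjusted p = 4.44e-04, adjusted p = 0.516 with an estimated correlation). The death receptor Tnfrsf10b differed by -0.37 ± 0.15, Ddit4, an inhibitor of mTOR signalling, by -0.66 ± 0.33 and Bbc3 by -0.21 ± 0.14. Genes of the Hippo pathway, which reads cell position in the early embryo, were called higher, with 13 of 18 higher and a median of 0.06 (adjusted p = 0.0488, adjusted p = 0.516 with an estimated correlation). The kinase Stk4 differed by 0.15 ± 0.05, Amot, a scaffold protein of the pathway, by 0.17 ± 0.09 and Ccn1, a target of YAP, by 0.29 ± 0.16. Both other tested probe sets of Amot and 2 of the 3 others of Ccn1 had the opposite sign. With the replicate number as a block the Hippo list had an adjusted p of 0.0581 and was not called. It was also lost with the mean of all probe sets of a gene, at 0.742, and with the software signal, at 0.658. Leaving out 1 array ended it for any replicate of biopsy or untreated except untreated replicate 5, for replicate 2, 3 or 5 of CMF_acid, for acid replicate 3 or 4 and for CMF replicate 5, with an adjusted p of up to 0.250. The p53 call was lost without untreated replicate 4 (adjusted p = 0.0824), and the junction call without untreated replicate 2 (0.222) or acid replicate 4 (0.0825). Glycolysis genes, 15 of 17 higher with a median of 0.06, had an adjusted p of 0.0745.

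Single genes that did not pass in acid against untreated included Il17rd, an inhibitor of fibroblast growth factor signalling, at 0.30 ± 0.06, Dgcr8, a component of the microRNA processing complex, at 0.51 ± 0.13, and the kinase Map2k6 at 0.50 ± 0.14. Il17rd and Dgcr8 were each called Present in 1 of the 4 untreated arrays, and their other tested probe sets had the opposite sign. Dgcr8 had a low log2 signal, 2.64 to 2.70 in acid arrays other than replicate 5, which stood at 3.39. Kif14, a kinesin of cell division, stood at -0.55 ± 0.14 and Hesx1, with a low log2 signal of 3.06 to 3.26 in the acid arrays, at -0.66 ± 0.22. Limma and ordinary least squares each called 0 probe sets, with 296 and 286 at an unadjusted p under 0.05 and a lowest adjusted p of 0.9999. Il17rd was called without acid replicate 5, at 0.37 (adjusted p = 0.0321), and Zfp78 without untreated replicate 5, at -0.57 (adjusted p = 1.12e-04). Without CMF_acid replicate 5, 0 probe sets were called, and junction genes (adjusted p = 3.03e-04) and p53 targets (adjusted p = 0.00267) were the lists called, both at an adjusted p = 0.479 with an estimated correlation.

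Embryos given both exposures without removal of a cell were compared with untreated embryos. No list was called, and the lowest adjusted p of 0.355 was shared by oxidative phosphorylation genes (19 of 26 lower, median -0.06 log2), p53 targets (15 of 19 lower, median -0.19) and zygotic genome activation genes (5 of 7 higher, median 0.16). This absence of calls depended on the filter, since lists were called with no detection filter, a setting fixed in advance. Primitive endoderm markers had 14 of 20 lower and a median of -0.06 (adjusted p = 0.406). In CMF_acid replicate 3 alone, Tcstv1, Tcstv3 and Zfp352, genes of the early cleavage stages, had log2 intensities of 8.06, 6.90 and 8.36, against means of 2.62, 2.25 and 2.87 in the other 19 arrays. CMF_acid replicate 5 stood apart over many genes. Without CMF_acid replicate 5, 3 lists were called. Cholesterol synthesis genes were higher, with a median of 0.22 (adjusted p = 1.89e-05, adjusted p = 0.741 with an estimated correlation). Immediate early genes were higher (adjusted p = 0.00911, adjusted p = 0.615 with an estimated correlation). Primitive endoderm markers were lower (adjusted p = 0.0277, adjusted p = 0.774 with an estimated correlation). The omitted array had the lowest cholesterol score of all arrays, -0.55 against -0.25 for the next. Its immediate early score was also the lowest, -0.36 against -0.33. Taking it out by itself raises the group's mean for these lists, so the 2 higher calls were not taken as support for a rise. Single genes that did not pass included the homeobox gene Homez at 0.44 ± 0.11 and the nuclear receptor Ppard at 0.45 ± 0.12 (SE, n = 4), and, on the lower side, Os9, a lectin of protein quality control in the endoplasmic reticulum, at -0.52 ± 0.13, the DNA exonuclease Exo1 at -0.54 ± 0.15 and Msl1, part of a histone acetyltransferase complex, at -0.42 ± 0.12. The other tested probe set of Os9 and 2 of the 3 others of Msl1 had the opposite sign. Limma called 0 probe sets with 683 at an unadjusted p under 0.05 and a lowest adjusted p of 0.834, and ordinary least squares called 0 with 732. Without CMF_acid replicate 4, Fxyd6, a regulator of the sodium pump, was called at 0.44 (adjusted p = 0.0422), and without untreated replicate 5 Zfp78 was called at -0.48 (adjusted p = 0.00116).

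**Figure D3:**
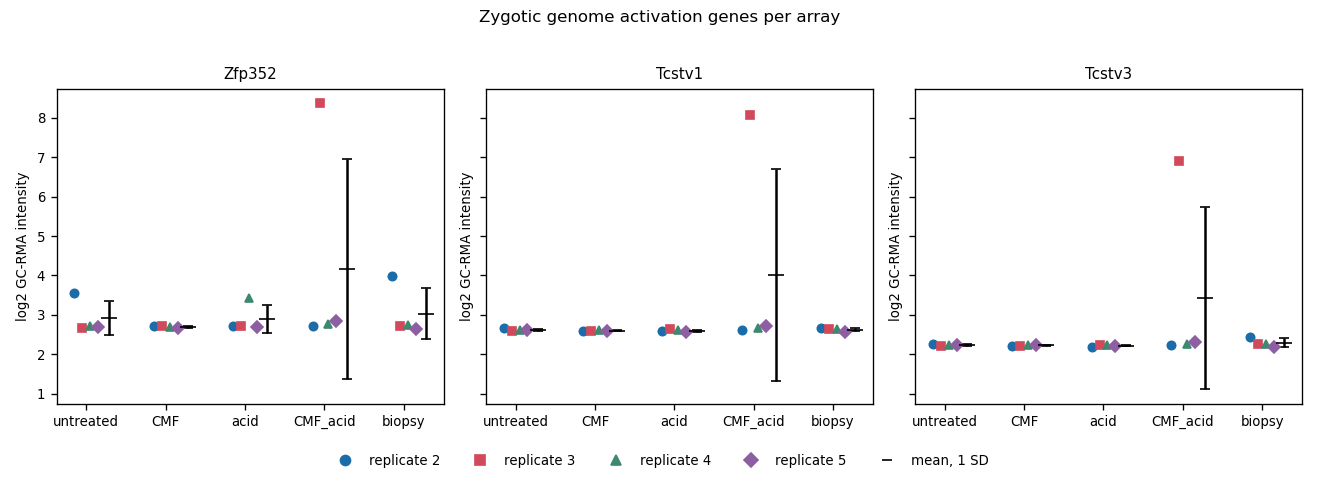
Log2 intensity of Zfp352, Tcstv1 and Tcstv3 is plotted by group, 1 point per array with bars for the group mean and 1 SD (n = 4). In CMF_acid replicate 3 these genes lie far above the other 19 arrays, with Zfp352 at 8.36.

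Biopsied embryos were compared with embryos given both exposures to separate the removal of the blastomere. Markers of the inner cell mass and epiblast had 15 of 22 members lower and a median of -0.06 log2 (adjusted p = 0.248). Within them Gdf3 differed by -0.43 ± 0.12, Spic, a transcription factor, by -0.37 ± 0.15, Utf1, a chromatin factor of pluripotent cells, by -0.41 ± 0.17 and Zfp42 by 0.24 ± 0.13 (SE, n = 4). Primitive endoderm markers had 16 of 20 lower and a median of -0.11 (adjusted p = 0.151), with Cubn at -0.60 ± 0.20 and Col4a1 at -0.23 ± 0.12. Of the oocyte transcripts, Nlrp5 differed by 0.30 ± 0.08 and passed when adjusted over the list alone (adjusted p = 0.0268), but it was called Present in 0 CMF_acid arrays and 2 biopsy arrays, so its size was not measured on the CMF_acid side. With all arrays no list was called. Without CMF_acid replicate 5, which had the lowest epiblast score of its group, 6 lists were called lower in the biopsied embryos. Epiblast markers then had a median of -0.14 and an adjusted p of 2.38e-04, and adjusted p = 0.0389 with an estimated correlation. The omission was chosen after seeing the data. Taking out the lowest epiblast score of CMF_acid by itself raises that group's mean, so these p-values were not taken as support for the call. The others were cholesterol synthesis (adjusted p = 5.26e-04), primitive endoderm markers (0.00941, median -0.13), ribosomal proteins (0.0134), the cytoskeleton (0.0244) and oxidative phosphorylation (0.0413), each at an adjusted p = 0.836 with an estimated correlation. CMF_acid replicate 5 also had the lowest scores of its group for cholesterol synthesis, the cytoskeleton and oxidative phosphorylation. The calls of these lists were therefore not taken as support either.

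Single genes that did not pass in biopsy against CMF_acid were led by Tmx3 at 0.66 ± 0.12, Prnp at 0.72 ± 0.16, Tmem167, a small protein of the secretory pathway, at 0.45 ± 0.10 and Brwd3, a bromodomain protein, at 0.47 ± 0.11. Adam15, a membrane metalloprotease, stood at -0.17 ± 0.04, the transcription factor Klf7 at -0.43 ± 0.11 and the autophagy gene Atg13 at -0.41 ± 0.11. The other tested probe set of Prnp had the opposite sign, as had 2 of the 4 others of Tmem167 and 1 of the 2 others of Brwd3 and of Klf7. Limma called 0 probe sets, with 1881 at an unadjusted p under 0.05, 1216 higher and 665 lower, and a lowest adjusted p of 0.617. Ordinary least squares called 0 with 1647. Without CMF_acid replicate 5 there were 0 calls and 739 at an unadjusted p under 0.05.

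The interaction asked whether both exposures together differed from the sum of each alone. Junction genes were lower by camera, with 22 of 26 members lower and a median of -0.20 log2 (adjusted p = 0.0315, adjusted p = 0.930 with an estimated correlation). The junction adhesion molecule F11r stood at -0.61 ± 0.33, occludin (Ocln) at -0.71 ± 0.42 and the polarity kinase Prkci at -0.20 ± 0.12 (SE, n = 4). The call was lost without CMF_acid replicate 5 (adjusted p = 0.119), whose junction score was -0.36 against a lowest of -0.13 in the other arrays. It was also lost without untreated replicate 2 or 3, CMF replicate 4, acid replicate 4 or CMF_acid replicate 3 or 4, at up to 0.391, and with the mean of all probe sets of a gene, at 0.0963. Single genes that did not pass included the meiotic gene Rec114 at 0.51 ± 0.13, the autophagy scaffold Rb1cc1 at -0.58 ± 0.16 and the dynein heavy chain Dync2h1 at -0.92 ± 0.25. Both other tested probe sets of Rb1cc1 had the opposite sign. Limma called 0 probe sets, with 868 at an unadjusted p under 0.05 and a lowest adjusted p of 0.779. Ordinary least squares called 0 with 2496. Without untreated replicate 5, Zfp78 was called at 0.61 (adjusted p = 0.00342).

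Over the mean of the 4 treatments, primitive endoderm markers were lower than in untreated embryos by camera, with 16 of 20 members lower and a median of -0.09 log2 (adjusted p = 9.33e-04, adjusted p = 0.521 with an estimated correlation). Mean list scores were 0.108 ± 0.17 in untreated, 0.039 ± 0.21 in CMF, 0.072 ± 0.23 in acid, -0.055 ± 0.05 in CMF_acid and -0.164 ± 0.15 in biopsied embryos (SD, n = 4 each). Biopsy had the lowest mean and acid the one nearest to untreated. Arrays ranged from -0.13 to 0.26 in untreated, from -0.15 to 0.31 in CMF and from -0.09 to 0.40 in acid. The order of the treatments was not tested. Cubn differed by -0.27 ± 0.16 and Col4a1 by -0.14 ± 0.09 (SE). Oxidative phosphorylation genes were lower, 24 of 26, with a median of -0.04 (adjusted p = 0.00129, adjusted p = 0.521 with an estimated correlation), and Atp5o, a subunit of ATP synthase, differed by -0.10 ± 0.07. Targets of p53 were lower, 15 of 19, with a median of -0.11 (adjusted p = 0.00358, adjusted p = 0.521 with an estimated correlation), and Ccng1, a cyclin induced by p53, differed by -0.20 ± 0.17. Mean p53 scores were 0.104 ± 0.19 in untreated, -0.026 ± 0.28 in CMF, -0.090 ± 0.19 in acid, -0.076 ± 0.16 in CMF_acid and 0.088 ± 0.25 in biopsied embryos (SD, n = 4 each). The biopsy mean thus hardly differed from the untreated mean. Without untreated replicate 4 the primitive endoderm call had an adjusted p of 0.177 and the p53 call one of 0.481. Without untreated replicate 2 the oxidative phosphorylation call was at 0.317 and the p53 call at 0.274. With the software signal the oxidative phosphorylation call was at 0.233 and the p53 call at 0.0596. Limma called 0 single probe sets, with 235 at an unadjusted p under 0.05 and a lowest adjusted p of 1, and ordinary least squares called 0 with 207. Cdc27 at 0.23 ± 0.06 and Hesx1 at -0.57 ± 0.17 were among the lowest unadjusted p-values. Hesx1 had a low log2 signal, 3.06 to 3.26 in acid arrays and 3.13 to 3.26 in biopsy arrays other than replicate 2, which stood at 4.30. The median level of the tested probe sets was 7.82, so the falls of Hesx1 in CMF, acid and this mean rest on weak signals. Without untreated replicate 5, Zfp78 was called at -0.52 (adjusted p = 2.94e-05). The F test for any difference among the 5 groups called 0 probe sets by limma and 0 by least squares, with 462 and 485 at an unadjusted p under 0.05 and a lowest limma adjusted p of 0.974.

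Changes after biopsy were set against those after each exposure to see whether they were shared. No probe set was called in any comparison, so the overlap of calls was 0 for all 3 pairs. At an unadjusted p under 0.01 in both comparisons, biopsy shared 0 probe sets with CMF, 1 with acid and 1 with CMF_acid in the same direction. Independent lists would share 0.0344, 0.0433 and 0.0842, and unchanged groups simulated against the same untreated arrays shared 7.49, 7.25 and 7.50 on average and at most 12, 13 and 13 in 100 simulations. The log2 differences correlated at 0.436, 0.319 and 0.152, beside simulated values of 0.500, 0.501 and 0.500, and the covariances were 0.00862, 0.00647 and 0.00446 beside simulated 0.0181, 0.0182 and 0.0181. The simulation treated the arrays as independent, whereas arrays of the same number deviated together and such deviations cancel between group means. Its counts and covariances can thus be too high as a baseline, by an amount that was not simulated. This does not cover the correlations, and the cause of their gap to the simulated values was not tested. None of these gaps was read as an absence of shared effects. With the untreated arrays split between the comparisons, the correlations averaged -0.133, -0.194 and -0.194. Each treated group holds every replicate number, whereas each part of the untreated arrays holds only some. Deviations shared by a number thus enter the compared differences with opposite sign and push the correlation below 0. These negative values therefore decide nothing about shared effects.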

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

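The tests of explanations in this part, and the counts over other splits of the arrays, were chosen after the result was seen. In 326 groups of 4 arrays or values, 28 held an array far from the other 3 by Dixon's test, where chance marks about 1 in 20 groups, or 16.3 here. Of the 28, 4 lay in CMF_acid replicate 5.

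In CMF_acid replicate 5, 1125 probe sets lay more than 1 log2 below the lowest of the other 19 arrays and 47 above the highest, while no other array had more than 6 below or 32 above. Within its group it had a Gapdh ratio of 3.99 against 3.51 to 3.53, inside the 3.08 to 4.30 of all arrays, an epiblast score of -0.26 against 0.06 to 0.09 and an immediate early score of -0.36 against 0.06 to 0.14, both just below the -0.21 and -0.33 of the lowest other arrays, while its junction score of -0.36 lay below a lowest of -0.13 and its score of the 4 cumulus and granulosa markers, 0.44, above a highest of 0.10. Against a cause in GC-RMA, its mean correlation with the other arrays was 0.966 with the software signal, below the lowest of 0.986 elsewhere. At the 1245 probe sets where it lay more than 1 log2 outside the 16 arrays of the other groups, the other 3 CMF_acid arrays shifted by 0.550% of its shift (median, -3.74% to 3.09% per array), which largely restates that the array stands apart from its group. An effect of the treatment on that pool stays open, as does poorer RNA or amplification as a candidate explanation, since its actin ratio of 4.22 exceeded the 3.06 of the next array.

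In CMF_acid replicate 3 the score of zygotic genome activation genes was 2.16, against -0.20 to 0.01 in its group and at most 0.20 in the other 19 arrays. The array had 15 genes more than 1 log2 above all others, among them Tcstv1, Tcstv3, Zfp352, Tdpoz1 and AF067061, some of which belong to families of near-identical copies whose probes may cross-hybridise. An artifact of GC-RMA is argued against by the median excess of 2.65 log2 over the next array in the software signal. The scores of the other 3 CMF_acid arrays, which differed from the remaining groups by -0.0200 log2, only restate that the array stands apart from its group, so an effect of the treatment stays open. An embryo or cell that still held maternal transcripts could not be told apart from one without them, since the oocyte score lay 1.04 SDs above the mean of the other arrays.

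Primitive endoderm markers were called lower after biopsy by camera at the preset correlation and not with an estimated correlation (adjusted p = 0.0907), and of the 35 splits of the 8 arrays only 1, the real one, gave the list so small a camera p, at 9.27 as -log10 against at most 6.96 in the others. Because the list was 1 of 26, the smallest p of any list was also counted, and 2 of 35 splits had one as small, with 10.8 as the highest of the others, so chance is not excluded for a list singled out as the lowest of all. The software signal kept the call (adjusted p = 2.49e-06, with 6.74e-11 to 0.743 over all alternatives), which argues against GC-RMA as the whole cause, while unequal 3 prime signal stays open, since the Gapdh ratio hardly differed (3.48 ± 0.371 in biopsy, 3.69 ± 0.472 in untreated, SD, n = 4) and the median of -0.24 log2 with it as a covariate decides nothing. Fewer inner cell mass cells of every kind stay open, since primitive endoderm minus epiblast scores differed by -0.18 log2 (exact permutation p = 0.114), and although the difference was below 0 in 4 of 4 same-numbered pairs, from -0.25 to -0.14, an exact sign-flip test of 4 pairs gives no p under the 0.125 found and the numbers are not known to pair these arrays. Whether removal of the blastomere or the exposures go with the lower markers could not be told apart either, since biopsy and CMF_acid scores differed with an exact permutation p of 0.229.

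A count of 0 is reached by every split by construction, so the splits say nothing about chance where 0 was called. This holds for the probe sets of every comparison, where 35 of 35 splits called at least 0, and the highest of the other splits were 1 in biopsy against untreated, 1 in CMF, 0 in acid, 1 in CMF_acid and 36 in biopsy against CMF_acid. For the interaction, the mean of the 4 treatments and the F test it was 100 of 100 drawn splits, with highest counts of 86, 467 and 3. The split with 36 set biopsy replicates 2 and 3 with CMF_acid replicates 3 and 5 against the rest. The one with 467 set CMF_acid replicate 5, untreated replicate 5, CMF replicate 4 and acid replicate 4 against the rest. These splits were picked as the highest, and in each the smaller or first set holds CMF_acid replicate 5, which stands apart. Whether they reflect a structure of the arrays other than the groups was not tested. Chance could not be excluded for the lists called, since 10 of 35 splits reached the 5 of biopsy (highest other 7), 29 of 35 the 1 of CMF (8) and 13 of 35 the 3 of acid (8), and of the 100 drawn splits 75 reached the 1 of the interaction (7) and 27 the 3 of the mean of the 4 treatments (7). In CMF_acid and in biopsy against CMF_acid 0 lists were called, which 35 of 35 splits reach by construction, with 5 and 6 as the highest of the others. In acid against untreated, where the numbers pair the arrays, 3 of the 8 splits that part all 4 pairs called at least 3 lists, with 8 as the highest of the others, and the splits that part fewer pairs called at most 7.

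For the junction list, the interaction, which asks whether both exposures together depart from the sum of each alone, had a median of -0.20 log2 (adjusted p = 0.0315). The adjusted p = 0.930 with an estimated correlation, and without CMF_acid replicate 5 the median was -0.11 (adjusted p = 0.119). Other list scores with an array apart were trophectoderm markers in biopsy replicate 2 (0.18 against -0.08 to -0.05), zygotic genome activation genes in biopsy replicate 2 (0.20 against -0.16 to -0.11) and the oxidative stress response in biopsy replicate 5 (-0.0480 against 0.0293 to 0.0359). The cytoskeleton score of biopsy replicate 4 was -0.10 against -0.02 to -0.01, and the ribosomal score of CMF replicate 3 was -0.0745 against -0.00280 to 0.00237.

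The remaining 19 values were single log2 intensities of named genes, where chance would mark 8.05 of 161 groups. In untreated arrays Lars2 stood at 3.89 in replicate 2 (others 4.63 to 4.77) and Nlrp5 at 6.09 in replicate 4 (6.27 to 6.29). Vmn2r29 at 5.09 and Rb1cc1 at 8.21 stood apart in untreated replicate 5, and Il17rd at 7.02 and Kdm2a at 4.19 in untreated replicate 3. In CMF arrays Parpbp at 9.06 (9.29 to 9.30), 4930513N10Rik at 3.02 and Dcaf8l at 4.64 stood apart in replicate 4, Rab31 at 2.88 in replicate 3 and Jam2 at 2.29 in replicate 2, on a different probe set of that gene than the 1 named for biopsy. In acid arrays Hesx1 at 3.06 and Rec114 at 7.45 stood apart in replicate 4, and Dgcr8 at 3.39 (2.64 to 2.70) and Dync2h1 at 7.08 in replicate 5. In biopsy arrays Dop1a stood at 7.80 in replicate 3, Hesx1 at 4.30 in replicate 2 (3.13 to 3.26) and Adam15 at 5.21 in replicate 5. Tcaim stood at 9.24 in CMF_acid replicate 5 (9.33 to 9.34).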

How the results depend on the processing

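The settings without CMF_acid replicate 5 where not fixed in advance, the block combined with that omission, and the exact permutation of list scores were chosen after seeing the data. No setting called more than 1 probe set in any comparison. With the software signal, acid against untreated called 1 probe set with no gene name (adjusted p = 0.0149) and the F test called the same 1 (adjusted p = 0.0341), while lists fell to 1 for biopsy, 0 for CMF and 1 for the mean of the 4 treatments. Camera with an estimated correlation and fry called 0 lists in biopsy, CMF, acid, the interaction and the mean of the 4 treatments, and exact permutation of the scores called 0 in biopsy, CMF and acid. For the permutation, 0 calls were nearly fixed in advance by its smallest possible p, so they decide nothing. With no detection filter, lists called were 0 for CMF, 10 for acid, 9 for CMF_acid and 7 for the interaction. The mean of all probe sets of a gene left 0 for the interaction. At an unadjusted p under 0.01 in both comparisons the overlap of biopsy was 1 with acid and 1 with CMF_acid. In all these the cause was not tested, except that the looser threshold itself admits more probe sets. Of the named genes 2 changed sign with the software signal, Adap1 in acid to -0.0491 log2 and Rec114 in the interaction to -0.0843. Both summaries rest on the same scans, so low signals near background, such as Zfp78, limit both. Median centring moved an array by at most 0.27 log2.

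Leaving out 1 array in turn, probe sets called ranged from 0 to 1 in biopsy, CMF, acid, CMF_acid, the interaction, the mean of the 4 treatments and the F test, and from 0 to 0 in biopsy against CMF_acid and in the overlaps. The calls were Zfp78 without untreated replicate 5, Il17rd without acid replicate 5 and Fxyd6 without CMF_acid replicate 4. Lists called ranged from 1 to 6 in biopsy, 0 to 2 in CMF, 1 to 8 in acid, 0 to 3 in CMF_acid, 0 to 6 in biopsy against CMF_acid, 0 to 1 in the interaction and 2 to 4 in the mean of the 4 treatments.

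With the replicate number as a block, 0 probe sets were called in all comparisons and lists called were 4 for biopsy, 1 for CMF, 2 for acid, 0 for CMF_acid, 0 for biopsy against CMF_acid, 1 for the interaction and 3 for the mean of the 4 treatments. In biopsy the call not made with the block was the cytoskeleton list (adjusted p = 0.0797). In acid, where the numbers pair the arrays, the block changed no other call than the Hippo list. Elsewhere the arrays were treated as sharing only a number. Yet all 20 arrays correlated best with an array of their own number, and 30 of the 40 same-numbered pairs had a correlation over 0.1. The median was 0.205 against -0.0727 for other pairs. Limma called 1056 probe sets for the number, in a test chosen after the data were seen. Deviations thus went with the number, although the labels do not say what it stands for. The primitive endoderm score was lower in biopsy than in untreated in 4 of 4 same-numbered pairs, and the list kept its camera call with the block at the preset correlation (adjusted p = 1.10e-07). Without the block, the list was not called at an estimated correlation. The replicate block without CMF_acid replicate 5 gave 2 lists for biopsy, 0 for CMF, 3 for CMF_acid, 5 for biopsy against CMF_acid, 0 for the interaction and 5 for the mean of the 4 treatments, and the lowest adjusted p of a probe set in biopsy was then 0.134.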

Other observations

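The 3 relations between genes or scores in this part were chosen after the values were seen. Between pools of the same group, some genes of known function varied far more than the median spread of 0.16 log2 (SD over 19 arrays, without CMF_acid replicate 5). Alcam, a cell adhesion molecule, ranged from 4.54 in biopsy replicate 3 to 9.47 in biopsy replicate 2, a within-group SD of 1.26. Chac1, a glutathione-degrading enzyme of the integrated stress response, had an SD of 1.18, Adh1, an alcohol dehydrogenase, one of 1.01, and Sox17, a transcription factor of the endoderm, one of 0.97, from 4.79 in untreated replicate 3 to 8.08 in acid replicate 2.

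Expression differed more with the replicate number than with treatment, in a test chosen after the data were seen. Limma called 1056 probe sets for the number with all arrays and 2394 without CMF_acid replicate 5, whereas the comparisons between groups called 0 in both cases. Rrbp1, a ribosome receptor of the endoplasmic reticulum, had means of 10.27, 9.90, 10.24 and 9.63 in the arrays numbered 2, 3, 4 and 5 (adjusted p = 3.04e-04). Idi1, an enzyme of sterol synthesis, had means of 11.94, 11.34, 12.17 and 11.91 (adjusted p = 0.00133), and Tpp1, a lysosomal peptidase, 12.32, 12.27, 11.89 and 12.54 (adjusted p = 0.00166). What the numbers stand for is not given in the sources used here.

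The labels give the sex as female for 19 of the 20 samples, whereas transcripts of the Y chromosome were called Present in all 20 arrays. Xist, which silences an X chromosome in female cells, had a mean log2 of 13.86, from 13.27 in acid replicate 3 to 14.48 in untreated replicate 2. Kdm5d had a mean of 6.96, Eif2s3y of 10.84 and Uty of 7.09, each lowest in biopsy replicate 2 and highest in biopsy replicate 5. Xist was lower in arrays where the mean of the 3 Y-linked genes was higher, over the 20 arrays with r = -0.737 (permutation p = 1.30e-04, adjusted p = 3.90e-04 over the 3 relations) and rho = -0.758 (permutation p = 1.60e-04, adjusted p = 4.80e-04). Without the 2 arrays farthest in Xist r was -0.760, within groups -0.734 and within replicate numbers -0.752. This is consistent with pools that held male and female embryos in different shares, a hypothesis tested on the same data, and the label may refer to the donor animals.

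A lag in development was tested as a hypothesis by setting primitive endoderm scores against oocyte scores. Across the 20 arrays r was -0.220 (permutation p = 0.352, adjusted p = 0.352) and rho -0.385 (permutation p = 0.0968, adjusted p = 0.0968), with r = -0.345 without the 2 farthest arrays and -0.0614 within groups, so a less advanced stage of some pools could not be told apart from its absence. Egln3, an oxygen-sensing hydroxylase, and Ndrg1, a gene that responds to low oxygen, formed the third relation computed. Their r was -0.703 over the 20 arrays, -0.760 within groups and -0.103 within replicate numbers, so it went mostly with the number. Both were picked from the genes that varied most, so the relation was not taken as a result.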
